A study of Batkoa obscura with 6 samples.

How the data were processed

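RNA-seq was made by the submitters on an Illumina HiSeq instrument from 3 liquid cultures and 3 mycotized aphid cadaver samples of 1 strain of Batkoa obscura. Per the labels' protocols, cultures were shaken at 120 rev/min in a 150-mL flask at 24 ± 1 °C for 4 days, then filtered, washed and frozen, and cadavers were kept at 24 ± 1 °C for 24 to 48 h and frozen. Total RNA was extracted with RNAiso Plus and libraries followed standard Illumina protocols, per the labels. The labels describe triplicates and do not say whether these came from separate flasks or separate groups of aphids. P-values therefore measure the spread between these libraries, which may be technical.

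The deposited table holds FPKM values that the authors computed for 76643 transcripts in 6 libraries, rounded to 2 decimals. The identifiers have the format of the Trinity assembler, with 1 transcript for each of 76643 assembled genes in 52803 clusters. Some identifiers carry a transcript number above 1, so other transcripts of a gene may have been left out of the table. The aligner, the quantification tool, their versions and any filters are not given in the sources used here. FPKM divides by the mapped fragments of a whole library. In a cadaver these can include aphid fragments, and a larger aphid share then lowers the FPKM of each fungal transcript, and a value can differ between libraries with no change within the fungus. Summed FPKM was 814955, 830309 and 806767 in cultures 1 to 3 and 604128, 743127 and 752962 in cadavers 1 to 3. A value of 0 has no known number of fragments behind it and is reported as listed at 0. No counts are given, so no counting interval or detection floor was computed.

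Relative depth was recovered from the values. Between FPKM 0.5 and 2 the values of a transcript are multiples of what 1 fragment is worth, and comparing these steps between pairs of libraries gave their depth ratios. The pairwise ratios differed from the fitted depths by at most 0.009 log2 units, and the deepest library had 1.34 times the depth of the shallowest. On simulated data the largest error was 0.0007 log2 units. Absolute depth remained unknown.

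The comparison of cadaver minus culture used limma on log2(FPKM + 1), with lmFit and eBayes with a trend, a two-sided test and Benjamini-Hochberg adjustment over all transcripts tested. Transcripts entered where FPKM was at least 1 in at least 3 of the 6 libraries, which left 18012. A transcript was called at an adjusted p below 0.05. Differences are on the log2(FPKM + 1) scale, which understates the change of transcripts with low values. Library measures were compared with two-sided exact permutation tests. The test, the filter, the naming rule and most alternatives for this comparison were fixed before the data were examined. The fits with no variance moderation, with the median of ratios without cadaver 1 and with the median of ratios over culture-expressed transcripts were added afterwards. The rule named, among called transcripts whose groups did not overlap, the 2 with the largest rise and the 2 with the largest fall, by identifier, since nothing in the table pairs identifiers with gene names. For the same reason 24 keyword lists of gene functions fixed beforehand were not applied, and no function is given for any transcript.

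The classes and every analysis of them were added after the values had been seen. A transcript was culture-expressed where its culture mean was at least 0.5 FPKM, at least 1% of its cadaver mean, and its mean over all 6 libraries at least 1 FPKM. The limit of 1% of the cadaver mean caps the size of a rise within the class. The limit on the mean over all 6 libraries admits rises and leaves out falls among transcripts with a low culture mean. Transcripts at 0 in all 3 cultures and above 0 in a cadaver formed a class of their own, and the remaining transcripts with a culture value formed the trace class. For the comparison within the culture-expressed class, each library was divided by its median of ratios over 6279 transcripts of the class, which gave factors of 1.14, 1.07 and 1.06 for cultures 1 to 3 and 0.497, 1.15 and 1.35 for cadavers 1 to 3. The same limma test was then run on all 7893 transcripts of the class.

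Limma's prior degrees of freedom were infinite for the deposited values, so that the test used a variance that depended on mean level alone, and 3.41 for the rescaled class. The median SD within groups on the log2 scale was 0.04 in cultures and 0.72 in cadavers for the deposited values, and 0.18 and 0.25 for the rescaled class. The 0.04 reflects the many tested transcripts at or near 0 in culture, 6068 of them at 0 in every culture. It does not measure how well expressed transcripts agreed between cultures. Both fits were tested on simulated data with the average spread of the real libraries at each level, drawn independently for each transcript. Changes were given only to transcripts above a minimum level. A shift shared by many transcripts of a library, such as that of cadaver 1, and the rescaling step were not simulated. In the fit of 18012 transcripts, 0 of 68 transcripts changed 2-fold, 16 of 66 changed 4-fold and 61 of 66 changed 16-fold were recovered, with 2 false calls. In the fit of 7893 culture-expressed transcripts the numbers were 27 of 68, 66 of 66 and 66 of 66, with 10 false calls. In these simulations a change of 2-fold was thus often missed. The counts of false calls need not hold for the real libraries.

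Library agreement was checked before averaging. At most 5.48% of values were identical between any pair of libraries, and each library was kept as a separate replicate. Pearson correlations of log2(FPKM + 1) across transcripts, which are not independent replicates, were 0.990 to 0.994 between cultures, 0.967 between cadavers 2 and 3, and 0.878 and 0.860 between cadaver 1 and cadavers 2 and 3. Over the culture-expressed class the cadaver pairs gave 0.948, 0.945 and 0.972. Alternatives covered the pseudocount, the filter, the scaling, the variance model, a block for replicate number, the class limits and leaving out each library. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.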

Results

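RNA was sequenced from the aphid-pathogenic fungus Batkoa obscura, also known as Conidiobolus obscurus, in 2 settings, with 3 libraries in each. The culture libraries came from mycelium grown for 4 days in shaken Sabouraud dextrose broth with yeast extract. The cadaver libraries came from mycotized aphids, insects overgrown by the fungus after live aphids had received conidia, the spores that spread the infection, and had been kept for 24 to 48 h. The table held FPKM values (fragment counts scaled by transcript length and by the mapped fragments of the library) for 76643 assembled transcripts, of which 8557 were listed at 0 in all 6 libraries. It carried assembly identifiers and no gene names, and it did not mark which transcripts belonged to the fungus and which to the aphid. Transcripts are therefore described below by where and how strongly they were detected. The absolute number of fragments per library was not given in the sources used here. The steps between low FPKM values gave depths relative to culture 1 of 1.04 for culture 2 and 1.00 for culture 3, and of 1.18, 0.956 and 0.882 for cadavers 1 to 3.

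The comparison between cadavers and cultures addressed which transcripts accompany growth of the fungus in its host. Cadavers held many transcripts that were not detected in culture. These can include aphid transcripts, which a culture does not hold and which the table does not mark. On average 21370 ± 1723 transcripts reached FPKM 1 in a cadaver (SD, n = 3) and 7769 ± 46.9 in a culture (SD, n = 3), a 2.75-fold difference. FPKM was at least 1 in all 3 cadavers and listed at 0 in all 3 cultures for 6068 transcripts, and 12 transcripts showed the opposite. The cadaver-only transcripts had a median cadaver mean of 4.55 FPKM, 1026 reached 10 FPKM, 9 reached 100 FPKM, and the highest stood at 168 FPKM. Requiring 0 in every culture leaves out abundant transcripts: among those higher in cadaver 1 by at least 0.6 log2 units, 9.57% at 1 to 3 FPKM in cadavers were above 0 in a culture, and 97.6% at 100 to 300 FPKM. Together the 6068 cadaver-only transcripts took 11.8%, 4.00% and 3.29% of summed FPKM in cadavers 1, 2 and 3. The 12 culture-only transcripts had a median culture mean of 2.05 FPKM, and 3 of them reached 10 FPKM. The culture-only count was 19 without cadaver 1 and 22 without cadaver 3. An exact permutation test of the number of transcripts at FPKM 1 gave p = 0.1 (two-sided), the smallest value that 3 against 3 libraries allow, with every cadaver above every culture.

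Transcripts expressed in culture made up most of summed FPKM in cadavers 2 and 3 and less in cadaver 1. Transcripts were sorted into a culture-expressed class of 7893, a class of 49095 listed at 0 in every culture, and a trace class of 11098 that had some culture value but did not meet the limits of the culture-expressed class. Culture-expressed transcripts held 99.8% ± 0.0181 of summed FPKM in cultures (SD, n = 3) and 66.4% ± 23.4 in cadavers (SD, n = 3). Their share was 39.4% in cadaver 1, 78.3% in cadaver 2 and 81.3% in cadaver 3. Trace transcripts held 44.8%, 15.8% and 14.0% of the same cadavers, and transcripts at 0 in culture held 15.8%, 5.88% and 4.70%. The class was defined from the culture values, so a share near 100% in cultures and a lower one in cadavers follow from its definition, and the difference was not tested. Without cadaver 1 the cadaver mean was 79.8%.

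**Figure D1:**
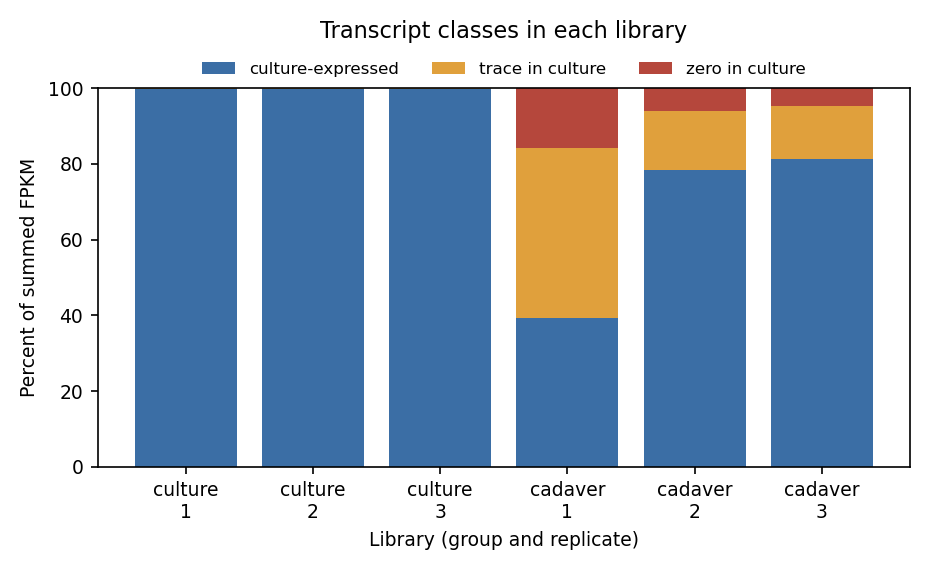
Percent of summed FPKM (vertical axis) held by each transcript class in each of the 6 libraries (horizontal axis), stacked to 100%. Culture-expressed transcripts fill 99.8% of each culture, 39.4% of cadaver 1, 78.3% of cadaver 2 and 81.3% of cadaver 3.

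In the deposited FPKM values, most culture-expressed transcripts did not pass the test, and falls in that class outnumbered rises, a balance that turned when each library was given the same class sum. All 6068 tested transcripts at 0 in culture were higher in cadavers, with a median log2 difference of 2.33. In the trace class 4000 of 4133 were higher and 29 lower, with a median of 3.31. Of 7811 culture-expressed transcripts tested, 523 were higher and 915 lower, with a median of -0.20. The filter admitted a transcript at 0 in all cultures only where FPKM was at least 1 in all 3 cadavers, and trace transcripts were mostly defined by a culture mean far below the cadaver mean. The direction of the first class was thus set by the selection, and that of the second largely so. Over all classes limma called 11535 of 18012 tested transcripts at a Benjamini-Hochberg adjusted p below 0.05, with 10591 higher (91.8%) and 944 lower. Of these, 11486 differed at least 2-fold. That share follows largely from the test, which recovered 0 of 68 simulated changes of 2-fold. A transcript that did not pass can therefore have changed by about 2-fold. The rises had a median log2 difference of 2.63 and the falls of -1.52. Among the culture-expressed transcripts tested, the 3 values of one group lay outside the range of the other for 2379 (30.5%, where chance gives 10%). Quantile normalization gives each library the same distribution of values, which removes an average rise by construction. It turned the overall split, to 3302 higher (43.6%) and 4272 lower. Requiring FPKM 1 in all 6 libraries gave 282 higher and 435 lower. Of the 6282 transcripts that this filter left, 6279 were culture-expressed, so it took out nearly all of the other 2 classes. With the main filter, the count of falls was 540, 570 and 611 without culture 1, 2 and 3.

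The transcripts with the largest rises were abundant in cadavers and over 1000-fold lower in culture. TRINITY_DN28147_c0_g1_i1 stood at 17694 ± 5743 FPKM in cadavers and 9.33 ± 2.54 FPKM in cultures (SD, n = 3 each), a 1896-fold difference. TRINITY_DN21280_c0_g1_i1 stood at 1846 ± 816 FPKM and 0.46 ± 0.251 FPKM, a 4012-fold difference. On the log2(FPKM + 1) scale the differences were 10.73 ± 0.57 and 10.23 ± 0.52 (SE), with limma Benjamini-Hochberg adjusted p of 2.89e-76 and 6.62e-82, and each was higher in 3 of 3 cadavers. Both belong to the trace class. Like most transcripts of that class, both were highest in cadaver 1, where culture-expressed transcripts were mostly lower. In cadavers 1 to 3 the first stood at 24165, 15712 and 13205 FPKM, and the second at 2786, 1423 and 1328 FPKM. Whether they belong to the fungus or the aphid is not known, so these rises need not be changes within the fungus. Among 230 transcripts with a culture value above 0, selected for a cadaver mean of at least 100 FPKM and a higher level in cadaver 1, the median culture value was 0.0611% of the cadaver value. The largest falls were of TRINITY_DN36259_c1_g1_i1 and TRINITY_DN36259_c1_g2_i1, from one assembly cluster. Their culture means were 112 ± 42.2 and 84.6 ± 66.2 FPKM (SD, n = 3), and both were listed at 0 in cadavers 1, 2 and 3. Their log2 differences were -6.75 ± 0.51 and -6.12 ± 0.51 (SE), with limma Benjamini-Hochberg adjusted p of 8.18e-38 and 3.90e-31. The size of these 2 differences depends on the pseudocount, as does that of TRINITY_DN21280_c0_g1_i1, which was 8.32 with a pseudocount of 5 and 12.02 with 0.01, then above the 10.88 of TRINITY_DN28147_c0_g1_i1. The 4 other transcripts in the cluster of each could share fragments with it. The very small adjusted p values follow from an infinite prior degrees of freedom in limma's variance model. Over all alternatives tried for the 4 named transcripts, the limma Benjamini-Hochberg adjusted p was at most 0.00768, and at most 0.0149 in rescaled values. Both were reached with each transcript's own variance. The 4 were picked as extremes of the same values, which favours agreement between alternatives. The 2 falls could not turn, being at 0 in every cadaver. Of the 4, requiring FPKM 1 in all 6 libraries left only TRINITY_DN28147_c0_g1_i1 to test.

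**Figure D2:**
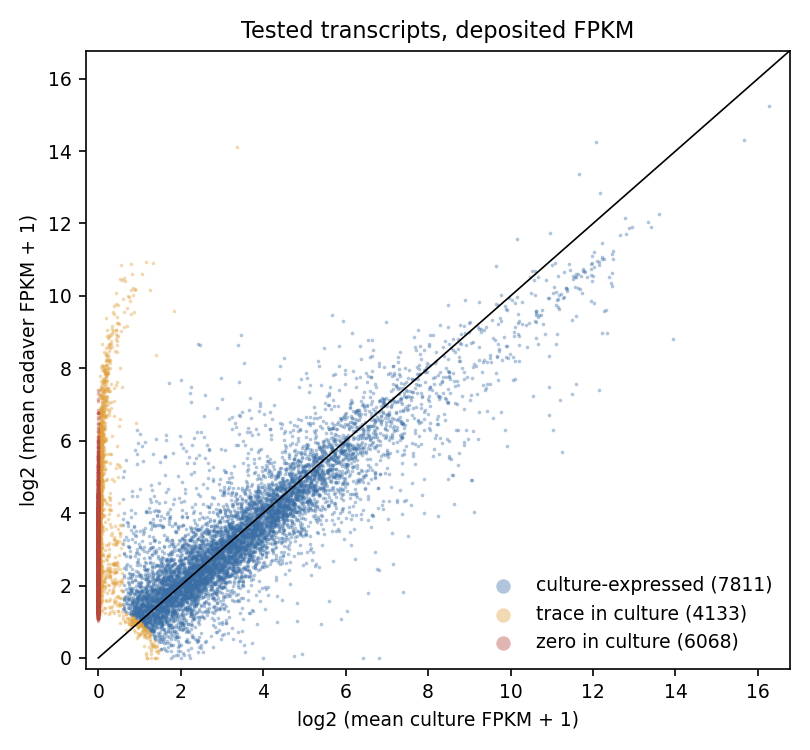
Mean cadaver level against mean culture level, both as log2(FPKM + 1), for the 18012 tested transcripts, one point each, coloured by class; the line marks equal levels. The 6068 transcripts at 0 in culture lie on the left edge, and the 7811 culture-expressed transcripts spread along the line.

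Within the culture-expressed class, similar numbers of transcripts rose and fell once each library was rescaled to the class. The rescaling set the median difference of the class near 0 (-0.01), so these changes are relative to the typical culture-expressed transcript. Higher levels in cadavers were found for 1410 of 7893 transcripts and lower levels for 1488. Of the 2898 called, 1473 differed at least 2-fold, with 715 higher and 758 lower. Rises of at least 8-fold numbered 99 and falls of that size 58. Both transcripts with the largest falls named above also fell after rescaling, with limma Benjamini-Hochberg adjusted p of 3.01e-05 and 0.000312, and the log2 difference of TRINITY_DN36259_c1_g1_i1 was -6.63 ± 0.27 (SE). Groups did not overlap for 4095 of the 7893 transcripts (51.9%, where chance gives 10%) and for 2884 of those called. This comparison was added after the values were seen. The balance rests on the scaling: with equal class sums in each library 3712 were higher (86.1%) and 601 lower, and with no rescaling 447 were higher (38.9%) and 701 lower. It also rests on the class limits, which favour rises at low levels. With a culture mean of at least 1 FPKM in place of the limits of 0.5 FPKM and of the mean over all libraries, 1227 were higher and 1547 lower. Without culture 1 the test called 1773 transcripts, 822 higher and 951 lower, and without culture 2 it called 930 higher. Without cadaver 1 it called 2986, with 1524 higher and 1462 lower. The small majority thus changed side, in a split that the rescaling holds near even. Of these calls, 2595 were shared with the full set and had the same direction.

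The most abundant culture-expressed transcripts were lower in cadavers relative to the rest of the class. Of the 119 transcripts with a mean of 1000 FPKM or more, 95 fell and 6 rose in the rescaled values, with a median log2 difference of -1.01. Between 100 and 1000 FPKM, 181 of 492 fell and 83 rose, with a median of -0.27, but with equal class sums this band turned, to 97 lower and 209 higher with a median of 0.36. From 10 to 100 FPKM, 559 of 2803 fell and 557 rose, against 209 and 1461 with equal class sums. From 1 to 10 FPKM, 645 of 4422 fell and 761 rose, against 242 and 2018. The class limit on the mean over all libraries favours rises at the low end of this band. Of the 100 transcripts most abundant in culture 88 fell and 4 rose, a set whose selection by culture level favours falls. Of the 100 most abundant in cadavers, whose selection favours rises, 69 fell, 7 rose and 24 were not called. With equal class sums the numbers were 49 and 6 for the culture set and 29 and 22 for the cadaver set. Among the 10 most abundant in cadavers 7 fell and 3 rose (4 and 3 with equal class sums). Falls also outnumbered rises above 1000 FPKM with equal class sums (49 against 14, median -0.37) and with no rescaling (39 against 2, median -1.26), although for the class as a whole equal class sums turned the split. The median of the transcripts at 1000 FPKM or more, minus that of transcripts under 10 FPKM and taken relative to the culture mean, was -1.05 ± 0.12 on the log2 scale in cadavers and 0.00 ± 0.11 in cultures (SD, n = 3 each). That culture value near 0 is set by the reference, which is the mean of the same cultures and so does not treat the groups alike. The 100 most abundant transcripts of the class in each library held 54.3% ± 1.46 of the class sum in cadavers and 63.2% ± 1.95 in cultures (SD, n = 3 each). Every cadaver lay below every culture in both measures, each with p = 0.1 in a two-sided exact permutation test, the smallest possible. The share of the 10 most abundant was 24.9% ± 0.859 and 25.7% ± 1.80 (SD, n = 3 each; exact permutation test, two-sided, p = 0.6), a difference smaller than the spread between replicates.

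Over all transcripts the share of summed FPKM in the leading transcripts was smaller in cadavers. The 10 most abundant transcripts of each library held 18.7% ± 4.02 of summed FPKM in cadavers and 25.6% ± 1.79 in cultures (SD, n = 3 each), and the 100 most abundant held 41.2% ± 6.17 and 63.0% ± 1.94. Every cadaver lay below every culture in both shares (exact permutation tests, two-sided, p = 0.1 each, the smallest possible). Cadaver 1 had the lowest share in its 10 most abundant transcripts, 14.0%, against 21.4% and 20.5% in cadavers 2 and 3.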

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

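All results on culture-expressed transcripts, the fits with no variance moderation and the medians of ratios without cadaver 1 or over that class were chosen after the data were seen. Of 325 alternative values, 287 stayed within 1.5 times the count or within the spread, or kept direction and significance. The majority direction of calls turned with quantile normalization and with FPKM 1 in all 6 libraries, and among culture-expressed transcripts with equal class sums. The small majority in that class also changed side without cadaver 1 (1524 higher, 1462 lower), where the rescaling holds the split near even. All 121 for the 4 named transcripts are in the 287, as their choice as extremes favours. In the deposited FPKM values, a filter of 5 FPKM in 3 libraries gave 4481 changed transcripts, 3785 higher and 4481 changed at least 2-fold. Requiring FPKM 1 in all 6 libraries tested 6282 transcripts and gave 717 changed, 282 higher, 435 lower and 713 at least 2-fold. Both filters test fewer transcripts. Quantile normalization gave 7574 changed, 3302 higher, 4272 lower and 7325 at least 2-fold. It gives each library the same distribution of values, which removes an average rise by construction. The causes of the following changes were not tested. A pseudocount of 5 left 6438 changes of at least 2-fold (845 among culture-expressed transcripts), and the median of ratios without cadaver 1 gave 1766 lower. With 1 library left out, lower transcripts numbered 540 to 1286 (540, 570 and 611 without culture 1, 2 and 3). The median log2 difference of all tested transcripts, 1.74 as deposited, was 2.12 with equal library sums, 1.90 with the median of ratios, -0.08 with quantile normalization, 0.62 with a pseudocount of 5, and 0.43 and -0.20 with the 2 filters.

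Among culture-expressed transcripts, no rescaling gave 1148 changed, 447 higher and 701 lower, and equal class sums gave 3712 higher and 601 lower, with the class median at 0.53 in place of -0.01. A class limit of 5 FPKM in culture tested 4865 transcripts and gave 1912 changed, 863 higher and 911 at least 2-fold. Leaving out 1 library gave 1773 to 2986 changed, 822 to 1524 higher and 951 to 1462 lower, each lowest without culture 1, and 930 higher without culture 2. With no variance moderation 10966 transcripts changed in the deposited values and 2041 in the class.

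Cadaver-only transcripts numbered 1174 at a limit of 5 FPKM and 9380 where absence meant under 0.1 FPKM. Culture-only transcripts numbered 22 at a limit of 0.5 FPKM, 3 at 5 FPKM and 13 to 22 with 1 library left out (19 and 22 without cadaver 1 and 3). The difference in the share of leading transcripts was -21.8 percentage points for the top 100, and that in transcripts detected was 38335 at 0.1 FPKM and 38459 above 0.

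Libraries with the same replicate number did not deviate together (correlations of -0.214, -0.0503 and -0.0678), and no cadaver correlated best with the culture of its own number. With replicate number as a block, 11155 transcripts changed in the deposited values and 2437 in the culture-expressed class. The alternatives planned for the gene lists were not run, because the identifiers carry no names. Depth differed by at most 1.34 times between libraries and its absolute value is unknown, so no detection limit can be given.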

Other observations

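The tests on cadaver 1, that of the spread of trace ratios and the overlap of leading transcripts were chosen after the results were seen. The slope of the trace values, both tests of transcripts at 0 in culture and the other groupings of libraries had their outcomes set out before they were run.

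Many of the leading transcripts of the culture-expressed class were shared by both settings. Of the 100 most abundant in culture, 79 were also among the 100 most abundant in cadavers, and 7 were shared among the top 10. In each cadaver the transcripts at 1000 FPKM or more lay below the cultures, with medians of -0.92 in cadaver 1, the least negative, and -1.13 in cadaver 3, the most negative. The share of culture-expressed transcripts in these libraries was 39.4% and 81.3%. With equal class sums the falls at 1000 FPKM or more numbered 49 and the rises 14, against 95 and 6 in the rescaled values.

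Cadaver 1 stood apart from cadavers 2 and 3. Culture-expressed transcripts were lower in it than in the mean of the others, with a median log2 ratio of -1.33 over 5243 transcripts, and transcripts at 0 in culture were higher, with a median of 1.46 over 3666. Depth as the cause was predicted to shift both classes the same way. Cadaver 1 had 1.29 times the depth of the others, and the 2 classes shifted in opposite directions. Because FPKM divides by the fragments of the library, a fall in a class goes with a rise elsewhere under any cause. The opposite shifts therefore do not decide for or against depth. A swap with a culture library would leave a culture with cadaver transcripts. The culture-expressed share, at least 99.8% in each culture, cannot show this, because the class is defined from the culture values. Transcripts at FPKM 1 or more numbered 7776, 7719 and 7812 in cultures 1 to 3. They numbered 23205, 21118 and 19787 in cadavers 1 to 3, which argues against a swap. A larger share of RNA not seen in culture stays open: 97.2% of transcripts lay on the side it predicts, but these are the ratios in which the pattern was seen, so they give no independent support. Whether such RNA was from the aphid, and whether the stage of infection within the 24 to 48 h mattered, was not tested.

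Many transcripts abundant in cadavers had trace values in cultures. Among 234 transcripts chosen from cadaver values alone, at 100 FPKM or more and higher in cadaver 1, 230 were above 0 in at least 1 culture and 171 in all 3, and the 230 had a median of 0.0611% of the cadaver level and medians of 0.0635%, 0.0450% and 0.0654% in cultures 1 to 3. Low expression by the fungus or shared sequence predicts ratios that vary widely, and the central 50% spanned 0.80 log2 units, which argues against either for the set as a whole; 6 transcripts at 1% or more stay open. Carry-over of a small fixed share of cadaver fragments into the culture libraries, at the bench or in sequencing, is a candidate explanation: the log2 culture value followed the log2 cadaver value with a slope of 0.92 (95% interval 0.83 to 1.01). A low culture value of a transcript abundant in cadavers may therefore not show expression in culture, and folds such as those of the largest rises could be larger than computed.

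Of the 6068 transcripts at 0 in culture, 107 (1.76%) were lower in cadaver 1 than in the mean of the others by at least 1 log2 unit, as culture-expressed transcripts were. Fungal transcripts made in the host and not in culture could look like this. Their median log2 ratio of cadaver 3 to cadaver 2 was -0.0778. Random lists of culture-expressed transcripts gave 0.10 to 0.28 and random lists of the other transcripts at 0 in culture gave -0.32 to -0.18 (central 95% of 10000 lists each). The set as a whole lay outside both ranges. The lists were not chosen for a low level in cadaver 1, as the set was, so this does not settle which kind the set resembles. A mixture of both kinds or RNA of another organism was not tested.

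Other groupings of the 6 libraries into 3 and 3 were compared with the real one. There are 10, too few for a share under 0.05. In limma on deposited values the real grouping gave 11535 changed transcripts, 10591 higher, 944 lower and 11486 at least 2-fold, and the highest of the other groupings gave 0 in each, with at most 93 at an unadjusted p below 0.05. For culture-expressed transcripts the real grouping gave 2898 changed, 1410 higher, 1488 lower and 1473 at least 2-fold, and the highest other gave 0 in each, with at most 270 at an unadjusted p below 0.05. In each case 1 of the 10 groupings, the real one, gave as many. Every other grouping mixes cadavers with cultures, so the difference between the settings widens the spread within its groups. Few calls could then be made, and the counts of 0 do not measure how many calls are false.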
